A study of Homo sapiens with 6 samples.

How the data were processed

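RNA sequencing was done on 6 samples of the human lymphoma line OCI-LY1, 3 with siRNA depletion of BCL6 and wild-type BCL6 put back, and 3 with RD2-mutant BCL6 put back. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed Illumina's TruSeq RNA procedure. Per the submitters' processing notes, CASAVA 1.8.2, STAR and edgeR were used with genome build hg19. The read counter, gene annotation, strand setting and rule for multi-mapping reads are not given in the sources used here. The authors deposited raw read counts per gene symbol, whole numbers with 1 column per sample, and replicates were not pooled. Because the strand setting is unknown, reads of overlapping and antisense genes cannot be assigned with certainty, and genes with near-identical copies may share reads. The table held 26 symbols that look like calendar dates, as spreadsheet software makes of some gene names, of which 17 were tested and 13 changed. They took 0.368% to 0.369% of counts in the wild-type rescue and 0.317% to 0.320% in the mutant rescue, were left in the library sizes and tests, and none is named.

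Samples were grouped by their labels as wild-type rescue and mutant rescue. Total counts per library ranged from 26298456 to 27574867, the 10 most abundant genes took 3.03% to 3.09% of counts, and TMM factors ranged from 0.987 to 1.02. How far precision was set by counting or by the spread between libraries was not tested by expression level. Of genes at or under 1 CPM on average 44.5% were called, and of genes with a mean log2 CPM above 6, 79.5%. Replicate libraries were compared by a chi-square test of their counts over genes with a pair total of at least 20. The statistic per degree of freedom was 1.60 to 3.01 in the wild-type rescue and 1.75 to 5.47 in the mutant rescue, so each pair differed by more than counting noise and all 6 libraries were kept as separate samples.

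The comparison used the counts as deposited in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its defaults, which kept 12406 of 23250 genes; 5824 of those left out had 0 counts in all libraries. Libraries were scaled with TMM, dispersions and the quasi-likelihood fit were estimated robustly, and glmQLFTest compared the rescues with both groups in 1 model and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Changed means past that threshold, and log2 fold changes are mutant rescue minus wild-type rescue. A rank or exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so single genes were tested in the model alone. The 28 gene lists, the design, the main test, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested against the other genes with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. List counts were also made with p-values adjusted over the list alone. Medians and counts of 27 lists were recomputed with 3 other scalings, and 1 list changed the sign of its median and 1 the side of its majority.

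Genes were named by a rule. It took 17 genes of prior interest, the 10 higher and 10 lower changed genes with the largest absolute log2 fold change, a mean raw count of at least 50 and no overlap between the groups, the 5 higher and 5 lower genes with the smallest adjusted p, and up to 4 members of each list with the smallest p. Some genes taken by the rule and 1 of the lists are not reported here. Genes named outside the rule were chosen after their values were seen, as the text says where they appear. The test was tried on simulated counts for the 12406 tested genes, with 50 genes changed at each of 4 fold sizes. In that simulation of the mutant against wild-type comparison, the quasi-likelihood test recovered 30% of genes changed 1.1-fold, 60% at 1.2-fold, 80% at 1.5-fold and 90% at 2-fold, with 5 false calls. Far fewer genes were changed there than passed in the data, and its dispersions followed the trend with expression level alone. These shares therefore do not give the sensitivity of the real comparison.

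Alternatives were RLE, upper-quartile and library size scaling, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, no filter on low counts, a minimum of 1 CPM in all libraries, the replicate number as a block, glmTreat against 1.2-fold, and leaving out each library in turn. Removal of trends with GC content and transcript length (smooth terms fitted with mgcv 1.9.3 and entered as offsets) and the trafficking list without S1PR1 were added after the data were seen. GC content and transcript length came from each gene's longest GENCODE v29 transcript, matched by symbol for 95.7% of tested genes. Gene order came from the RefSeq annotation of assembly GRCh38.p14, matched by symbol for 96.6%. Beyond this order no coordinates were used, because the counts were made on another build.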

Results

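Transcripts were measured by RNA sequencing in OCI-LY1, an established human cell line from a diffuse large B cell lymphoma, which is a tumour of mature B cells. The cells' own BCL6 was depleted with siRNA, and BCL6 was put back from an introduced copy that was either wild-type or mutated in RD2. BCL6 is the transcriptional repressor on which germinal centre B cells depend, and RD2 is a repression domain in the middle of the protein. Each rescue had 3 libraries. The wild-type rescue libraries held 27574867, 26477404 and 27487686 counts, and the mutant rescue libraries held 26314491, 26966183 and 26298456. Between 15097 and 15216 genes had at least 1 count in a wild-type rescue library, against 15377 to 15484 in a mutant rescue library. At these depths a floor of 3 counts corresponds to 0.109 to 0.114 CPM, that is counts scaled to library size, which covers counting error only. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

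The comparison of the mutant with the wild-type rescue gives the transcripts that differ between RD2-mutant and wild-type BCL6. Receptors that place B cells in the germinal centre were of particular interest. No library lacked a rescue, and an effect of RD2 cannot be told apart from a difference between cultures or in the amount of BCL6. The mutant rescue held far more transcript of the egress receptor S1PR1, the recombinase gene RAG1 and the plasma cell and activation factor IRF4, and less of the B cell surface marker MS4A1 (CD20) and the follicle-homing receptor CXCR5. On the lists fixed for this comparison, 34 of 40 mitotic genes, 33 of 47 interferon stimulated genes and 17 of 22 histone genes rose, while 50 of 50 ribosomal protein genes, 25 of 29 cholesterol synthesis genes and 18 of 21 heat shock genes fell. All fold changes below are given as mutant rescue relative to wild-type rescue, and values are TMM-scaled CPM as mean ± SD over n = 3 libraries. A lone number in parentheses after a gene symbol is its log2 fold change.

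BCL6 itself was abundant in every library, with 19069, 16998 and 18789 counts in the wild-type rescue and 14166, 13726 and 13827 in the mutant rescue. It was 1.31-fold lower in the mutant rescue (519.9 ± 8.71 against 679 ± 24.3 CPM; log2 fold change -0.38, SE 0.032; edgeR quasi-likelihood test, adjusted p = 7.90e-10). The gene-level counts do not separate what was left of the cell's own transcript from the introduced one.

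Of 23250 genes in the table, 12406 were tested and 8702 (70.1%) changed, 4386 of them higher and 4316 lower in the mutant rescue (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most of these changes were small, with a median absolute log2 fold change of 0.39. At least 2-fold changes were seen for 781 higher and 399 lower genes, and at least 8-fold changes for 62 higher and 22 lower genes. Before adjustment 8999 genes had a p under 0.05, and the values of the groups did not overlap for 8977 tested genes (72.4%), against 10% by chance with 3 libraries in each group. The first principal component held 87.2% of the variance of log2 CPM, and the common biological coefficient of variation was 3.34%. The count of changed genes therefore includes differences of a few percent, and against a minimum change of 1.2-fold (edgeR glmTreat) it was 4585.

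**Figure D1:**
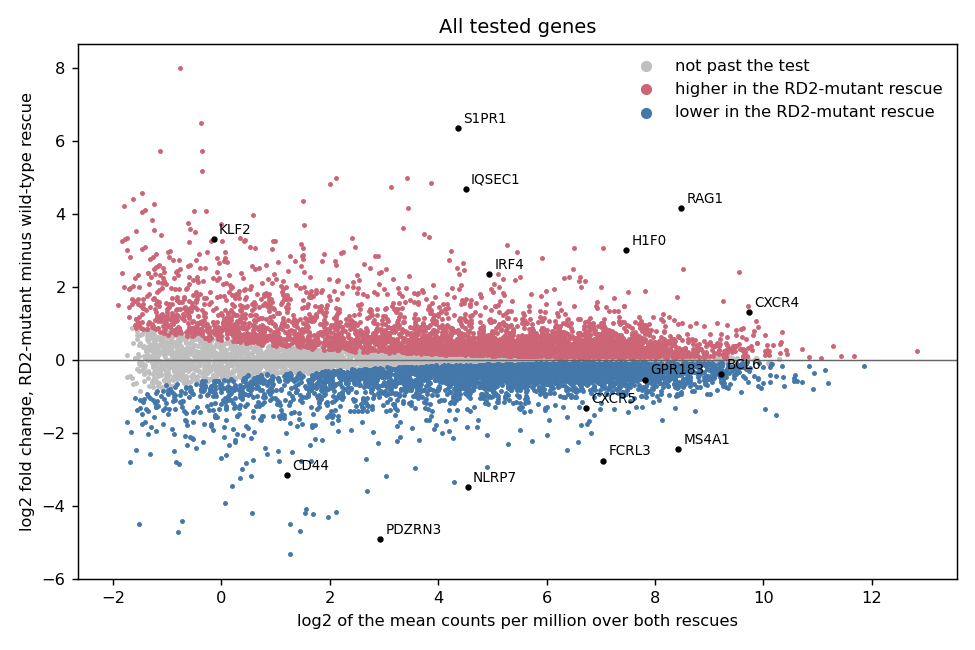
Log2 fold change of each of the 12406 tested genes (mutant minus wild-type rescue) against the log2 of its mean CPM over both rescues, with 1 point per gene, red for genes higher in the mutant rescue, blue for genes lower in it and grey for genes that did not pass the test. S1PR1 lies at 6.35, above every other labelled gene, and GPR183 lies below 0 at -0.54.

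The highest fold change among the genes singled out by size was that of S1PR1, followed by C10orf10 (4.99), AEBP1 (4.97), NAV3 (4.85) and LINC00163 (4.81) on the log2 scale. The other genes among the 10 largest increases were KIAA1324 (4.75), IQSEC1 (4.68), GAB1 (4.36), CSRP2 (4.16) and RAG1 (4.15), of which GAB1 encodes a signalling adaptor of receptor tyrosine kinases and RAG1 a subunit of the V(D)J recombinase. Several increases started near the detection limit in the wild-type rescue, such as C10orf10 with 7, 8 and 6 counts and GAB1 with 9, 4 and 8. The sizes and ranks of such fold changes are uncertain. RAG1 rose 17.8-fold, from 38.2 ± 0.805 to 679 ± 44.6 CPM. The 10 largest decreases were those of NAV2 (-5.33), PDZRN3 (-4.92), NLRP4 (-4.68), NCS1 (-4.51) and TFPI2 (-4.31), together with KIF26B (-4.21), C4orf26 (-4.18), CAMP (-4.17), MUC16 (-4.08) and RAB25 (-3.59). Several of these were near the detection limit in the mutant rescue, such as NAV2 with 6, 1 and 2 counts against 110, 142 and 128 in the wild-type rescue. By adjusted p, the leading increases were those of the linker histone H1F0 (8.01-fold, from 39.4 ± 1.30 to 316 ± 3.42 CPM; edgeR, adjusted p = 8.49e-23), ARPP21 (2.48), the spectrin gene SPTBN1 (2.40), the transglutaminase gene F13A1 (3.07) and the death receptor gene TNFRSF21 (3.08). The leading decreases were those of MS4A1 (5.43-fold, from 583 ± 17 to 107 ± 4.0 CPM; edgeR, adjusted p = 4.14e-22), the Fc receptor-like gene FCRL3 (-2.76), NAPSB (-2.46), NLRP7 (-3.49) and CHI3L2 (-2.01). NAPSB is a transcribed pseudogene, and its reads may be shared with NAPSA, so its value is uncertain.

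Receptors that position B cells in lymphoid tissue moved in opposite directions. S1PR1, which draws lymphocytes out of tissue towards blood and lymph, was barely detected in the wild-type rescue (9, 14 and 17 counts) and reached 1056, 1105 and 1113 counts in the mutant rescue, an 81.6-fold increase from 0.496 ± 0.152 to 40.8 ± 1.24 CPM (log2 6.35, SE 0.11; edgeR, adjusted p = 9.65e-21). GPR183, the oxysterol receptor that guides B cells to the outer follicle, fell 1.46-fold, from 268 ± 9.78 to 184 ± 7.86 CPM (log2 -0.54, SE 0.037; edgeR, adjusted p = 3.33e-11). CXCR4, the dark zone receptor, rose 2.49-fold to 1217 ± 27.8 CPM, while CXCR5, which responds to the follicular chemokine CXCL13, fell 2.51-fold to 60.4 ± 2.54 CPM. S1PR2, which confines B cells to the germinal centre, rose 1.46-fold, from 59.5 ± 1.38 to 86.8 ± 0.737 CPM. CD69, which holds S1PR1 off the cell surface, rose 3.47-fold, and the adhesion molecule CD44 fell 8.97-fold to 0.461 ± 0.0960 CPM. The integrin subunit gene ITGA4 rose (0.95). Chosen after their values were seen, KLF2 (3.32), CCR7 (1.82) and S1PR4 (2.17) also rose, KLF2 being a transcription factor that drives S1PR1 expression. All 3 stayed low, at 1.65 ± 0.171, 1.93 ± 0.412 and 3.59 ± 0.597 CPM in the mutant rescue. Of the 25 tested genes on the list for germinal centre trafficking and retention, 11 rose, 8 fell and 6 did not pass the test, and 11 rose and 8 fell adjusted over the list alone. The list rose as a set, with a median log2 fold change of 0.11 (camera, adjusted p = 0.0349; adjusted p = 0.239 with an estimated correlation), but S1PR1 decided this call, since without it the adjusted p was 0.270. S1PR1 and GPR183 had been put on the list because the study is known to follow them, so it is not independent evidence of their direction.

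**Figure D2:**
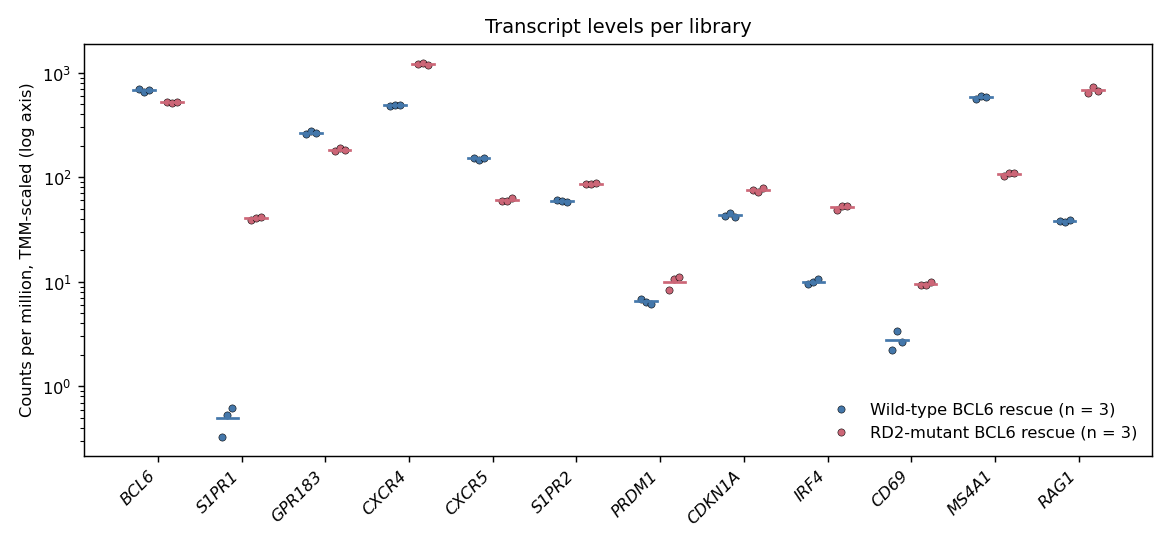
TMM-scaled CPM (log axis) of 12 genes in each library, with 1 point per library, blue for the wild-type rescue and red for the mutant rescue (n = 3 each), and a bar at each group's mean. The groups do not overlap for any of these genes, S1PR1 rising from 0.496 to 40.8 CPM and RAG1 from 38.2 to 679 CPM.

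Genes known to be repressed by BCL6 were more often higher than lower in the mutant rescue. Of 41 tested, 26 rose, 12 fell and 3 did not pass the test, and 27 rose and 12 fell adjusted over the list alone, with a median log2 fold change of 0.24 (camera, adjusted p = 0.00118; adjusted p = 0.309 with an estimated correlation). S1PR1 and GPR183 are on this list too, for the reason given above. IRF4 rose 5.12-fold, from 10.0 ± 0.575 to 51.4 ± 2.53 CPM, and the cell cycle inhibitor genes CDKN1A (43.1 ± 1.71 to 75.8 ± 3.60 CPM) and CDKN1B (1.49) rose 1.76-fold and 2.81-fold. PRDM1, the plasma cell regulator, rose 1.54-fold at a low level, from 6.48 ± 0.339 to 10.0 ± 1.39 CPM (SE 0.10 on the log2 scale; edgeR, adjusted p = 1.56e-05). BCL2 rose slightly (0.22), whereas the checkpoint kinase gene ATR (-0.64), the phosphatase gene DUSP5 (-1.41) and MYC (-0.51) fell. The largest fall on this list was that of CD44 (-3.16). PTPN6, a phosphatase gene chosen after its value was seen, fell by 1.82 on the log2 scale. CCND2 was at the detection limit, with 1, 1 and 11 counts in the wild-type rescue and 1, 2 and 1 in the mutant rescue, and was not tested.

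Of 32 genes for DNA damage sensing and repair, 9 rose, 14 fell and 9 did not pass the test, and 10 rose and 14 fell adjusted over the list alone, and the set test was not passed (median -0.07; camera, adjusted p = 0.561). Within it, the checkpoint kinase gene CHEK2 and the end-joining ligase gene LIG4 rose (0.64 and 1.12), and APEX1, of base excision repair, fell (-0.43).

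B cell stage genes were mixed. On the germinal centre B cell list, of 39 tested genes 23 rose, 12 fell and 4 did not pass the test, and 23 rose and 12 fell adjusted over the list alone, and the set test was not passed (median 0.29; camera, adjusted p = 0.270). EBF1, an early B lineage factor, and GCET2 rose (0.94 and 0.99), while MS4A1 and the transcription factor gene IRF8 fell (-2.44 and -0.92). On the plasma cell list, of 24 tested genes 9 rose, 13 fell and 2 did not pass the test, and 9 rose and 13 fell adjusted over the list alone, and the median (-0.19) had the opposite sign to the mean (0.05) and to the set test (camera, adjusted p = 0.917). The regulators XBP1 (1.70), IRF4 and PRDM1 and the receptor gene TNFRSF13B (2.48) rose, while the joining chain gene IGJ (-1.50) and the folding enzyme gene PDIA4 (-0.93) fell. Of 23 activation and memory genes, 11 rose, 8 fell and 4 did not pass the test, and 11 rose and 8 fell adjusted over the list alone, with IL2RG (0.92) among those that rose and CD44 among those that fell (median 0.07; camera, adjusted p = 0.119). Of 33 B cell receptor signalling genes, 19 rose, 10 fell and 4 did not pass the test, and 19 rose and 10 fell adjusted over the list alone (median 0.12; camera, adjusted p = 0.0517). The kinase genes PRKCB (1.82) and PIK3CD (0.95), the adaptor gene BANK1 (1.17) and the co-receptor gene CD72 (1.03) rose.

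Of 11 tested class II presentation genes, 3 rose, 5 fell and 3 did not pass the test, and 3 rose and 5 fell adjusted over the list alone (median -0.31; camera, adjusted p = 0.270). The peptide exchange genes HLA-DMA (-1.57) and HLA-DMB (-2.33), the invariant chain gene CD74 (-0.31) and IFI30 (-0.54) fell. Class II HLA transcripts were scarce in both rescues, with 373 to 481 counts per wild-type rescue library and 127 to 170 per mutant rescue library summed over the HLA-DR, DP, DQ, DM and DO genes. Of 18 class I presentation genes, 6 rose, 9 fell and 3 did not pass the test, and 7 rose and 9 fell adjusted over the list alone (median -0.01, which became 0.02 with library size scaling; camera, adjusted p = 0.380). B2M, the class I light chain, rose (0.69), and the peptide loading genes TAPBP (-0.62), CALR (-1.34) and PDIA3 (-1.03) fell.

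Cell cycle genes split by phase. Of 40 genes for G2 and mitosis, 34 rose, 2 fell and 4 did not pass the test, and 34 rose and 2 fell adjusted over the list alone, with a median of 0.37 (camera, adjusted p = 1.00e-09; adjusted p = 0.302 with an estimated correlation). The checkpoint kinase gene BUB1 rose 2.02-fold, the centromeric histone gene CENPA 2.12-fold, and the factor gene FOXM1 and the kinesin gene KIF20A 1.79-fold and 1.66-fold. Of 39 S phase genes, 7 rose, 25 fell and 7 did not pass the test, and 7 rose and 26 fell adjusted over the list alone, with a median of -0.16 (camera, adjusted p = 0.0145; adjusted p = 0.302 with an estimated correlation). The replicative helicase genes MCM4 (-0.72), MCM5 (-0.60) and MCM6 (-0.74) fell, and E2F2 rose (0.79). MKI67, the proliferation marker and a member of the mitosis list chosen after its value was seen, did not pass the test (1114 ± 2.75 CPM in the wild-type and 1058 ± 119 in the mutant rescue).

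Genes for protein synthesis fell as a group. All 50 tested cytosolic ribosomal protein genes on the list fell, and 50 fell adjusted over the list alone, with a median of -0.53 (camera, adjusted p = 1.03e-27; adjusted p = 0.0712 with an estimated correlation). Their share of all counts was 2.25% to 2.31% in the wild-type rescue libraries and 1.55% to 1.57% in the mutant rescue libraries, and RPS24 (-0.94), RPL10A (-0.90), RPS3 (-0.88) and RPL13 (-0.86) were the examples with the smallest p. Many ribosomal protein genes have processed pseudogenes that could take or give reads, so single values are less certain than the common direction. Of 31 genes for ribosome biogenesis and MYC targets, 0 rose, 30 fell and 1 did not pass the test, and 0 rose and 31 fell adjusted over the list alone, including SRM (-0.83), PES1 (-0.79), HSPD1 (-0.65) and GNL3 (-0.59), with a median of -0.46 (camera, adjusted p = 3.34e-10; adjusted p = 0.0712 with an estimated correlation).

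Metabolic genes on 3 lists mostly fell. Of 29 cholesterol and fatty acid synthesis genes, 3 rose, 25 fell and 1 did not pass the test, and 3 rose and 25 fell adjusted over the list alone, with a median of -0.41 (camera, adjusted p = 1.57e-09; adjusted p = 0.0789 with an estimated correlation). Their examples were the last-step reductase gene DHCR7 (2.43-fold lower), the lanosterol synthase gene LSS (2.16-fold), the fatty acid synthase gene FASN (2.14-fold) and the desaturase gene SCD (1.98-fold). SREBF1, a regulator of these genes chosen after its value was seen, fell by 0.94 on the log2 scale. Of 31 glycolysis and hypoxia genes, 7 rose, 20 fell and 4 did not pass the test, and 7 rose and 21 fell adjusted over the list alone, with ENO2 (-1.64), GPI (-0.73), ALDOA (-0.60) and ENO1 (-0.42) among the falls and a median of -0.28 (camera, adjusted p = 0.00316; adjusted p = 0.340 with an estimated correlation). Of 44 nuclear encoded respiratory chain genes, 2 rose, 28 fell and 14 did not pass the test, and 2 rose and 28 fell adjusted over the list alone, with COX7C (-0.60), SDHD (-0.49), ATP5A1 (-0.46) and ATP5B (-0.40) among the falls and a median of -0.18 (camera, adjusted p = 0.0040; adjusted p = 0.340 with an estimated correlation).

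Chaperone genes were mostly lower. Of 21 heat shock genes, 2 rose, 18 fell and 1 did not pass the test, and 2 rose and 19 fell adjusted over the list alone, with HSP90AA1 (-0.77), HSP90AB1 (-0.71), HSPH1 (-0.68) and FKBP4 (-0.67) among the falls and a median of -0.47 (camera, adjusted p = 6.95e-05; adjusted p = 0.302 with an estimated correlation). HSPB1, chosen after its value was seen, rose (1.39), and reads of the near-identical HSPA1A and HSPA1B cannot be assigned with certainty. On the unfolded protein and integrated stress response list, of 28 tested genes 16 rose, 11 fell and 1 did not pass the test, and 16 rose and 11 fell adjusted over the list alone (median 0.21; camera, adjusted p = 0.917). The chaperone and folding genes HSPA5 (2.63-fold), CALR (2.53-fold) and PDIA4 (1.91-fold) were lower, whereas XBP1 (3.24-fold) and DDIT4 (2.78-fold) were higher. The stress-induced factor genes DDIT3 (1.21) and ATF3 (1.87), chosen after their values were seen, rose as well.

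Interferon stimulated genes were mostly higher. Of 47 tested, 33 rose, 6 fell and 8 did not pass the test, and 33 rose and 7 fell adjusted over the list alone, with a median of 0.32 (camera, adjusted p = 1.61e-05; adjusted p = 0.0712 with an estimated correlation). IRF1, an interferon-induced transcription factor gene, rose 4.19-fold, and EPSTI1 (1.14), PARP14 (1.03) and SAMD9L (0.83) rose with it. Of 22 histone genes, 17 rose, 0 fell and 5 did not pass the test, and 17 rose and 0 fell adjusted over the list alone, with a median of 0.93 (camera, adjusted p = 1.41e-05; adjusted p = 0.0712 with an estimated correlation). H1F0, HIST1H2BJ, HIST1H2BD and H2AFZ rose 8.01-fold, 4.51-fold, 2.63-fold and 1.31-fold, and counts of replication-dependent histones can depend on near-identical copies and on whether their mostly non-polyadenylated transcripts were captured. Of 26 NF-kB targets, 10 rose, 11 fell and 5 did not pass the test, and 11 rose and 11 fell adjusted over the list alone; with library size scaling 13 rose and 10 fell, and the median (0.02) had the opposite sign to the mean (-0.16) and the set test (camera, adjusted p = 0.855). The adhesion molecule gene ICAM1 (2.08), the prostaglandin receptor gene PTGER4 (1.95) and BCL2L1 (0.92) rose, while the subunit gene REL (-1.30) fell. The cytokine genes TNF (-1.89), LTA (-1.53) and LTB (-1.55), chosen after their values were seen, fell. Of 25 immediate early genes, 12 rose, 7 fell and 6 did not pass the test, and 12 rose and 7 fell adjusted over the list alone (median 0.20; camera, adjusted p = 0.412), with CD69 and IER5 (0.72) higher and DUSP5 lower. The chromatin corepressor list also held acetyltransferase genes, which are not corepressors. Of its 36 genes, 16 rose, 11 fell and 9 did not pass the test, and 16 rose and 11 fell adjusted over the list alone (median 0.06; camera, adjusted p = 0.550). HDAC9 (1.35), BCOR (0.91) and the acetyltransferase gene CREBBP (0.67) rose and CHD3, a remodeller of the NuRD complex, fell (-0.65). HDAC2 was 0.08 higher on the log2 scale (195 ± 8.32 against 184 ± 4.96 CPM; edgeR, adjusted p = 0.0444), a call lost in 9 of the alternative settings.

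**Figure D3:**
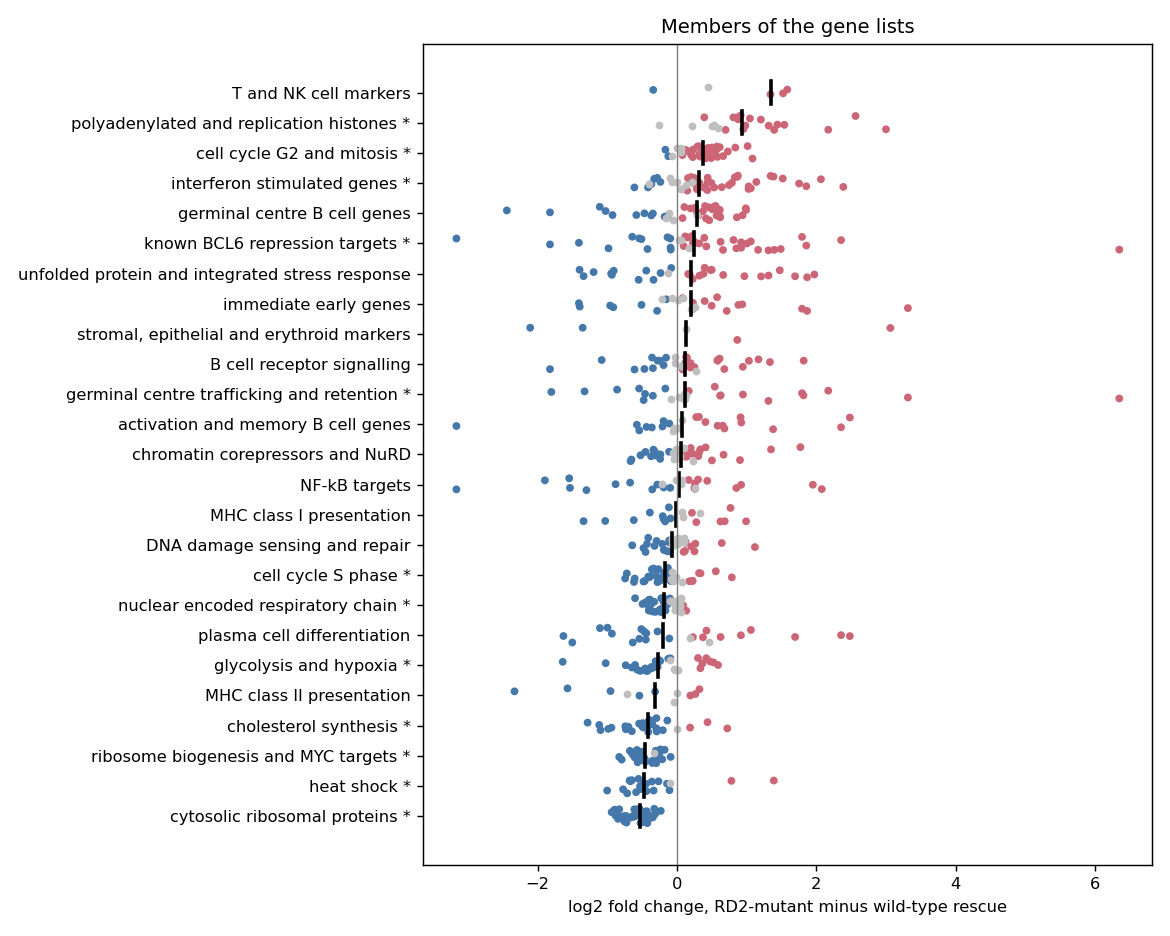
Log2 fold change (mutant minus wild-type rescue) of each tested member of 25 lists with at least 5 tested members, with 1 point per gene, red for higher, blue for lower and grey for not past the test, a black bar at each median and an asterisk on the 12 lists with a camera adjusted p under 0.05 at the preset correlation, none of which passed with an estimated correlation. Ribosomal protein genes lie entirely below 0 (median -0.53), while histone genes have a median of 0.93; with library size scaling the class I median changes sign to 0.02.

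Markers of other cell types were mostly too low to test. Of the 25 T and NK cell markers listed, 5 were tested, of which 3 rose, 1 fell and 1 did not pass the test, and 4 rose and 1 fell adjusted over the list alone (median 1.34; camera, adjusted p = 0.0823). IL7R (90.7 ± 4.26 to 230.3 ± 16.4 CPM), CD28 (1.52) and PRF1 (1.59) rose, and the kinase gene LCK fell (-0.34). Of 22 myeloid markers, 2 were tested and 2 rose, CD68 (0.58) and AIF1 (1.32), both under 4 CPM, and AIF1 lost its call in 5 alternative settings. Of 25 stromal, epithelial and erythroid markers, 5 were tested, of which 2 rose, 2 fell and 1 did not pass the test, and 2 rose and 2 fell adjusted over the list alone (median 0.14 and mean 0.12, opposite in sign to the set test; camera, adjusted p = 0.624). VIM and FN1 rose (3.07 and 0.87), and EPCAM and PECAM1 fell (-2.11 and -1.35). None of the 15 mitochondrially encoded transcripts listed was matched to a row, and this list was not analysed here. Across all lists, 13 passed camera with its preset correlation (6 higher and 7 lower). With a correlation estimated for each list 0 passed (5 at an unadjusted p under 0.05), so the group calls hold only in the preset form of the test. A higher estimate is not the reason for every loss. For the trafficking, interferon and histone lists the estimates (-0.025, -0.011 and -0.0085) were below the preset 0.01, while that of the mitosis list was 0.376. The fry test, which does not compare a list with other genes, called 22.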

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

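Removal of the GC content and length trend and the trafficking list without S1PR1 were chosen after the results were seen. The count of 8702 changed genes ranged from 7847 to 9094 over the other scalings, tests and filters apart from glmTreat, and from 8099 to 8916 when each library was left out in turn (4125 to 4466 higher, 3965 to 4450 lower). The settings shared 7649 to 8692 of its genes, except glmTreat. With glmTreat against a 1.2-fold change 4585 genes passed, 2383 higher and 2202 lower, since that test asks for more than a difference from 0. DESeq2 called 7858 genes, limma-voom 8697, no filter on low counts 9094 of 17426 genes tested, and the 1 CPM minimum 7847 of 10757. Leaving out each library, the log2 fold change of BCL6 lay between -0.41 and -0.37, that of GPR183 between -0.58 and -0.51 and that of S1PR1 between 6.12 and 6.56. All 3 kept their direction and passed in every setting run on them, with largest adjusted p-values of 3.87e-07, 1.88e-08 and 3.33e-15, except that the 1 CPM minimum removed S1PR1 before testing. Of 158 genes named in the text or by its rule and tested, 155 kept their side of the threshold, and no call changed direction. The exceptions were HDAC2, lost in 9 settings, AIF1, lost in 5, and MKI67, which passed without mutant replicate 1 (log2 fold change -0.16).

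With all libraries 13 lists passed camera, and 12 to 14 passed when a library was left out (5 to 7 higher, 7 lower each time), 12 or 13 of them shared with the 13. With an estimated correlation in camera 0 lists passed, 0 higher and 0 lower (5 at an unadjusted p under 0.05), and with fry 22 passed, 12 of them higher. For both changes the cause was not tested. A correlation above the preset 0.01 is argued against for the trafficking, interferon and histone lists, whose estimates were -0.025, -0.011 and -0.0085. As for fry, it asks another question, whether members move on balance without regard to other genes. Of 26 lists, 4 kept their side in every setting run on lists, and these had not passed. The trafficking list was lost in 5, among them limma-voom (adjusted p = 0.321), no filter on low counts, the 1 CPM minimum (0.404) and the list without S1PR1 (0.270). The list not reported here, 1 of the 13, was lost in 6, with adjusted p-values of 0.0505 to 0.288, among them without wild-type replicates 1 (0.0602) or 3 (0.0560). The B cell receptor list passed in 7, among them without wild-type replicate 2 (0.0404) and without mutant replicates 1 (0.0262) or 2 (0.0280). DESeq2, the likelihood ratio test, glmTreat and the removal of GC content and length trends were not run for lists. For lists only the likelihood ratio test among these had been planned, and it was left out because camera does not use the gene test.

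Replicate numbers paired the libraries in part, with correlations of same-numbered deviations of 0.14, 0.17 and -0.05. Numbers 1 and 2 correlated best with their own number and 3 did not. On the second principal component, numbers 1 to 3 of the wild-type rescue scored 8.86, -9.68 and 1.28. Those of the mutant rescue scored 8.29, -12.5 and 3.78, the same order, which the main model did not allow for. The replicate block gave 9285 changed genes and 15 lists. Among these lists were the B cell receptor list (camera, adjusted p = 0.0109) and the T and NK cell markers (camera, adjusted p = 0.0351). Genes at or under 1 CPM were called least often (44.5%), and whether depth set this was not tested.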

Other observations

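The tests of copy number, of repeat libraries, of GPR183 against a lower BCL6 level, of class II positive cells and of early lymphoid genes outside the fixed lists were chosen only after their results were seen. Apart from the tests of the lists fixed at the start, a number of early lymphoid genes were higher in the mutant rescue. RAG1, ARPP21 and DNTT drew attention first, DNTT (terminal transferase) having 2, 0 and 0 counts in the wild-type rescue and 39, 50 and 35 in the mutant rescue. A list of 25 other genes of B and T cell precursors was then written without looking at their values. Of 20 tested, 14 rose, 5 fell and DEPTOR (-0.18) did not pass, with a median log2 fold change of 0.47. CD34, FLT3, ERG, CD99 and IGLL1, also on that list, had at most 3 counts in any library of either rescue and were not tested. RAG2 rose 3.07-fold, VPREB1 of the surrogate light chain rose from 0.233 ± 0.150 to 1.64 ± 0.582 CPM, and CD9 (1.73), ZCCHC7 (1.62) and TCL1A (1.01) rose too. VPREB3, IKZF1, LEF1, SMARCA4 and CDC25A fell (-0.29, -0.09, -0.09, -0.18 and -0.12). Of the tested genes 6 also stood on a fixed list and all 6 rose. EBF1, FOXO1, TCF3, BACH2 and SPIB were on the germinal centre B cell list and IL7R on the T and NK cell list. These 6 are therefore not markers of precursors alone. Of the 14 on no fixed list 8 rose and 5 fell. All genes in this and the next paragraph were named after their values were seen, apart from those that the naming rule had taken.

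Targets of FOXO transcription factors, which act when PI3K signalling is low, were a further group. FOXO1 rose 1.45-fold, from 347 ± 7.52 to 504 ± 19.6 CPM, and the FOXO targets S1PR1, KLF2, CCR7, IL7R, RAG1, RAG2 and CDKN1B were among the genes described as higher. These targets were picked from genes already seen to rise, so they are not evidence for the group. RAG1, RAG2, IL7R and FOXO1 also belong to the early lymphoid genes above, so the 2 groups are not separate. Of 24 tested genes on a list of 26 further targets whose values had not been looked at, 16 rose and 5 fell, with a median of 0.29, while BCL2L11, FBXO32 and RBL2 did not pass (-0.05, 0.15 and 0.05). TXNIP (0.65), KLHL24 (0.81), CCNG2 (0.46) and YPEL3 (0.76) rose, and ERBB3 (-2.23), TNFSF10 (-0.83), GABARAPL1 (-0.60), SOD2 (-0.40) and CAT (-0.27) fell.

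Most tested genes differed between the rescues, 8702 of 12406. The tables argue against the choice among the scalings run as the cause, since the lowest count with another scaling was 8697. These scalings differed little, and a shift in total RNA per cell was not tested. GC content and length are argued against, as they explained 0.0706% of the variance of the fold changes and left 8719 calls when removed. So is copy number of large chromosome segments, since 0.744% of the changed genes lay in windows of 50 neighbouring genes with a median beyond 0.3. The highest window median was 0.780, on chromosome 6, and chromosome 12 reached 0.436, also beyond 0.3. What raised these windows and whether smaller segments differ were not tested. Splits of the 6 libraries into 3 and 3 are too few, at 10, for a share under 0.05. In these, 1 split, the real one, gave 8702 genes and the highest other gave 0 (edgeR, up to 157 genes at an unadjusted p under 0.05). Every other split mixed the rescues within each group, which puts their difference into the spread. A count near 0 there was thus likely in advance, and no conclusion is drawn from it. A coefficient of variation of 3.34% between libraries could also come from repeat libraries of 1 culture per rescue, in which case differences between cultures would count as effects of the mutant, and the labels leave this open. An effect of the RD2 mutation cannot be told apart from such a culture difference here.

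S1PR1 and GPR183 moved in opposite directions. For GPR183, another scaling is argued against by its log2 fold change nearest to 0, -0.52, while the lower BCL6 transcript stays open, since the fall of -0.54, opposite to a release from repression, is the observation itself and indirect effects were not tested. For S1PR1, a lower amount of BCL6 stays open, because 25 of the 39 other listed targets tested rose and 11 fell, past the threshold of limma's camera with its preset correlation (p = 0.00219) but not with an estimated correlation (p = 0.176), and a protein that represses less well would give the same picture, so the test does not separate amount from function. A wider rise of FOXO targets is a candidate explanation for S1PR1, as 66.7% of the unseen targets rose against 35.4% of all tested genes (two-sided Fisher exact test, p = 0.00215, Benjamini-Hochberg adjusted p = 0.00215 over 2 such tests; camera, p = 0.0370, and p = 0.398 with an estimated correlation). Whether FOXO activity changed was not measured.

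Of the unseen early lymphoid members 70% rose, against 35.4% of all tested genes (two-sided Fisher exact test, p = 0.00185, adjusted p = 0.00215; camera, p = 1.69e-07, and p = 0.00574 with an estimated correlation). Without the 6 members that also stood on a fixed list, all of which rose, 57.1% of 14 rose (two-sided Fisher exact test, p = 0.0987; camera, p = 2.07e-04, and p = 0.0169 with an estimated correlation), so the higher share rests in part on those 6. Cells of another, class II positive B lineage line are argued against by HLA-DRA, whose highest count in a mutant rescue library was 13 and in a wild-type rescue library 26. Cells of a T lineage line are argued against by CD3D, CD3E, CD3G, CD2 and CD7, whose summed counts in the mutant rescue libraries were 0.00734% of those of RAG1. A class II negative precursor line was not tested, and repeat libraries of 1 culture stay open here too.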
